A study of Mus musculus with 2 samples.

How the data were processed

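H3K9ac ChIP-seq was measured in 2 samples, biological replicates of midbrain from mouse embryos at embryonic day 13.5, which form 1 group per the labels. The labels call them biological replicates and name a separate tissue sample for each, pooled from embryos of both sexes, under the same donor entry. The deposited data used here were 4 peak lists in narrowPeak format on mm10: one per replicate, a pooled list and a list of replicated peaks. Per the read-me notes with the samples, each replicate's list was derived from that replicate's alignments and 1 further file, the pooled list from the alignments of both replicates and 2 further files, and the replicated list from the other 3 lists. What the further files are, the aligner, the peak caller and the rule for a replicated peak are not given in the sources used here. A candidate rule was checked on the lists: all 34630 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak were in the replicated list, but so were 5957 others.

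The authors' fold enrichment of each peak (a ratio, at 1.22 to 50.2 over the 4 lists) is not given a definition in the sources used here and was taken as a value within a list only. The deposited lists also give each peak's significance as −log10 p and −log10 q; the lowest −log10 p of any list was 2.01 to 2.03, and 69.0, 66.4, 80.3 and 98.6% of the peaks in the replicate 1, replicate 2, pooled and replicated lists had a −log10 q of at least 2. Because replicate and pooled peaks were called separately, replicates could be compared by overlap but not by signal at fixed sites. Peak lists hold no read totals, so the depth of each library is unknown and no interval that needs it is given. Any effect of depth on the share of unmatched peaks was not tested.

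Gene models were GENCODE M21 protein-coding genes on chromosomes 1 to 19, X and Y, 21911 symbols with 93504 transcript start sites; 27 symbols shared by more than 1 gene were treated as 1. Sequence came from GRCm38, the assembly that mm10 names, and every peak and gene ended within its chromosome. Peaks on scaffolds outside the assembled chromosomes were kept in the list totals, the candidate rule and the counts of replicated peaks that overlap each replicate. They were left out of all other comparisons. The Y chromosome was left out of that between X and autosomes, and signal tracks were not used here. A gene was called marked where a peak overlapped by at least 1 bp the 1 kb either side of any of its start sites. Peaks outside all such windows were called distal and assigned to the gene with the nearest start site to their centre, within 100 kb. Domains were replicated peaks joined across gaps of up to 1 kb, and a gene's domain was the widest at its start sites. The CpG ratio was the observed number of CpG over that expected from C and G in the 1 kb either side of the gene's 5' end, with a limit of 0.6.

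Replicate overlap and the promoter share were set against 100 random placements of the peaks on the sequenced part of their chromosome (one-sided). Marked shares of 27 gene lists, the regional comparisons, X against autosomes, CpG classes and replicated against other pooled peaks used two-sided Fisher's exact tests. Log domain widths and counts of distal peaks per list used two-sided permutation tests with 100000 resamples against other marked genes or all other genes. Adjusted p are Benjamini-Hochberg values within each family, with a threshold of 0.05, and genes near one another or in more than 1 list are not independent. The gene lists hold 511 different symbols, 23 of them in more than 1 list, and 1, Ahsp, was not in the annotation. Besides genes of progenitors, neurons, brain regions and signalling, they include markers of cells that the tissue could hold (endothelial, microglial, mesenchymal, erythroid, glial) and of other tissues (muscle, heart, liver, gut and pancreas, epidermis, germline).

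The lists, tests, windows and alternative settings were fixed before the data were examined, together with the rule for named genes: a fixed set of 27 genes, the 2 strongest marked and up to 2 unmarked members of each list, the 10 widest domains, the 10 highest promoter enrichments, the 5 genes with the most distal peaks and the 3 strongest distal peaks. Alternatives were a −log10 q of at least 2, the pooled list, each replicate's own list, windows of 0.5 and 2.5 kb, a single start site per gene, overlaps of 50%, equal numbers of peaks, merged peaks, gaps of 0 and 2.5 kb, distances of 50 and 500 kb, leaving out genes in more than 1 list, and matching within quintiles of CpG ratio or of the genome length nearest to a gene. Settings chosen after the data were seen were replicated peaks that overlap both replicates, leaving out 3656 genes that share a promoter window, and leaving out 2599 genes with under 80% of sampled promoter 32-mers found once in the genome.

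Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and pysam 0.24.0. Overlap counts were tested against bedtools 2.31.1 on 85195 peaks and did not differ at 1 bp, 50% of the peak or 50% of both peaks. List tests were tested on simulated data with the real 21911 genes and list sizes. In the marking test 91 of 100 lists planted at 98% marked and 79 of 100 planted at 25% were called in the right direction, with 5 of 340 unchanged lists called. In the CpG-matched test, run with random quintiles and lists of mostly marked genes, 89 of 90 lists planted at 50% marked and 1 of 180 unchanged lists were called. No higher share was planted there, so the power of that test for higher shares is unknown. In the width test 36 of 40 lists of doubled width and 1 of 68 unchanged were called, and in the distal test 40 of 40 lists given 3 more peaks and 3 of 68 unchanged.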

Results

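H3K9ac, the acetylation of lysine 9 on histone H3, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the midbrain of mouse embryos at embryonic day 13.5. At this stage the midbrain holds dividing progenitors beside newborn dopaminergic, GABAergic and glutamatergic neurons. H3K9ac is a mark of active promoters and of many enhancers. There was 1 group, with 2 biological replicates of tissue pooled from male and female embryos of strain B6NCrl, and no second tissue, stage or treatment. The measurement was therefore of where in the genome the mark lay, and the comparisons were made between the replicates, between fixed lists of genes and between parts of the genome. The authors' peak list held 85206 peaks for replicate 1, covering 43.9 Mb, and 72102 peaks for replicate 2, covering 39.7 Mb. Their pooled list held 92702 peaks, covering 54.2 Mb, and their list of replicated peaks held 40587, covering 41.0 Mb with a median width of 687 bp. Peak lists carry no read counts, so the depth of each library is unknown here. Intervals of percentages given below are exact Clopper-Pearson 95% intervals over genes or peaks. Those of odds ratios are 95% intervals by a large-sample normal approximation. Both cover counting error only. All positions are mm10, counted from 1, and the fold enrichment of a peak is the authors' value, used only to describe, rank or filter peaks within a list.

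Sox4, a transcription factor of newborn neurons, had the highest fold enrichment at its promoter (50.2) and lay in a domain of 7327 bp on chromosome 13, from 28946966 to 28954292. Actg1, which encodes cytoplasmic gamma-actin, followed with 48.1, then the RNA-binding protein gene Mex3b with 45.7 and the chromatin remodelling gene Arid1a with 45.3. The other genes among the 10 highest were Tnrc18, Sbk1, Midn, Sfpq, Sp3 and Brsk1, at 42.5 to 44.6. Of 21911 protein-coding genes, 14286 (65.2%, interval 64.6 to 65.8) had a replicated peak within 1 kb of a transcription start site and are called marked. Replicate 1's own list marked 14815 genes and replicate 2's own list 14590, and 14303 genes were marked in both. Of the 14286 genes marked in the replicated list, 14163 were also marked in each replicate's own list.

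Peaks at strong sites were shared by both replicates, and weak ones were mostly not. All of the strongest 10% of peaks in either replicate overlapped a peak of the other by at least 1 bp. The lowest shares were in the second weakest 10%, 18.7% of replicate 1's peaks and 24.4% of replicate 2's, and the weakest 10% stood at 23.7% and 30.7%. Across all peaks, 40244 of 85195 in replicate 1 (47.2%) overlapped a peak of replicate 2, against a mean of 3.02% when the peaks were placed at random on the same chromosomes. In the other direction the share was 40978 of 72086 (56.8%), against 3.51% at random, and 37.5% overlapped by at least 50% of both peaks. Both shares lay above all 100 random placements (one-sided permutation p = 0.0099, the smallest that 100 placements can give). Among overlapping peaks, the fold enrichment in one replicate and that of the strongest partner in the other had a Spearman rho of 0.756 from replicate 1 and 0.735 from replicate 2. These correlations are across peaks, which are not independent replicates, so no p was computed for them.

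**Figure D1:**
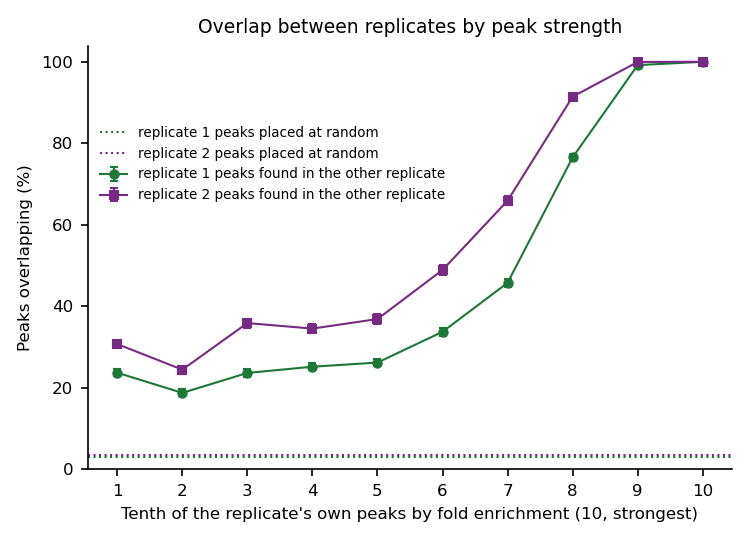
The percentage of a replicate's peaks that overlap a peak of the other replicate, on the y axis, against the strength of the peak, on the x axis, where each replicate's peaks were divided into 10 equal groups by fold enrichment. Bars are 95% Clopper-Pearson intervals and dotted lines the mean of 100 random placements. Replicate 1 stands at 23.7% in its weakest group, 18.7% in the next and 100% in its strongest, and replicate 2 at 30.7%, 24.4% and 100%.

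Pooled peaks at promoters were in the authors' replicated list more often than pooled peaks elsewhere. Of 27077 pooled peaks at promoters of protein-coding genes, 19791 (73.1%) were in the replicated list. Of 65612 pooled peaks away from promoters, 20786 (31.7%) were, an odds ratio of 5.86 (two-sided Fisher's exact test, p below what double precision can hold). Within quartiles of peak strength the gap was smaller. In the strongest quartile of pooled peaks by fold enrichment, 99.8% of promoter peaks and 98.8% of the others were replicated, in the next 60.0% and 54.3%, in the one after 16.3% and 14.3%, and in the weakest quartile 7.05% and 5.47%. Every replicated peak had the coordinates of a pooled peak, and 34805 of the 40587 (85.8%) overlapped peaks of both replicates by at least 1 bp. A further 3806 overlapped a peak of replicate 1 only, 1767 a peak of replicate 2 only and 209 a peak of neither. When pooled peaks were counted by overlap with replicate 1's peaks instead, the difference between promoter and distal peaks was 26.8 percentage points in place of 41.4.

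H3K9ac was concentrated at the start sites of protein-coding genes. Of 40577 replicated peaks on the assembled chromosomes, 19791 (48.8%) overlapped the 1 kb either side of a start site, against a mean of 5.82% for the same peaks placed at random, which is 8.38 times as many. The difference passed the permutation test (one-sided p = 0.0099, the smallest that 100 placements can give). Promoter peaks had a median fold enrichment of 9.62 and a median width of 1176 bp, and the 20786 other peaks 3.36 and 481 bp. The share was lower in each replicate's own list, at 32.3% and 35.7%, and in the pooled list, at 29.2%, all above their random placements. Among the 20786 distal peaks, 52.2% had their centre in an intron of a protein-coding gene, 8.86% in an exon and 38.9% between protein-coding genes, where these parts hold 35.7%, 3.63% and 60.7% of the sequenced genome. The strongest distal peak had a fold enrichment of 42.4 and lay on chromosome 5 from 123133696 to 123140707, between protein-coding genes and 4510 bp from the nearest start site, that of Rhof. The next was at 41.7, on chromosome 7 from 73555940 to 73558570, 15425 bp from a start site of Chd2. The third was at 39.5, on chromosome 12 from 27335382 to 27340128, where its centre lay in an exon 4819 bp from a start site of Sox11, a transcription factor of newborn neurons.

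Promoters of neural progenitor, neuronal and midbrain genes carried H3K9ac with very few exceptions. All 24 genes of the neural progenitor list were marked (interval 85.8 to 100%), with Msi1, which encodes an RNA-binding protein of neural stem cells, at a fold enrichment of 41.4, Id4 at 31.3 and Sox2, a progenitor transcription factor, at 23.7. All 26 genes of the midbrain patterning list were marked, and all but Wnt1 were also marked in replicate 2's own list. Not all 26 stayed marked when only peaks overlapping both replicates were counted. The list's share then exceeded that of other genes by 27.7 percentage points, in place of 34.8. That excess was 31.1 at a −log10 q of at least 2 and 31.5 with a window of 0.5 kb. En2 and Zic2 were the strongest at 22.7 and 21.7, Otx2, which sets up the forebrain and midbrain, stood at 21.7, En1 at 14.1, Pax5 at 7.46, Lmx1b at 5.86 and the floor plate gene Foxa2 at 4.63. Of 24 proneural and newborn neuron genes, 23 were marked (95.8%), including Cbfa2t2 at 28.9, Insm1 at 23.3 and the proneural gene Neurog2 at 10.2, while Neurod4 had no peak in any of the 4 lists.

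Neuronal genes of several transmitter types were marked in this tissue. All 24 postmitotic neuron genes had a peak, with Dpysl3 at 31.0, the neuronal tubulin gene Tubb3 at 29.9 and the microtubule-binding gene Dcx at 11.5. So did all 15 genes of the GABAergic lineage, with Lhx1 at 16.8, Slc32a1, the vesicular GABA transporter gene, at 15.6 and Gad2, which encodes a GABA-synthesising enzyme, at 14.2. All 14 glutamatergic midbrain genes were marked, among them Pou3f3 at 35.8, Tcf7l2 at 24.2 and Slc17a6, a vesicular glutamate transporter gene, at 13.2. Of 18 dopaminergic neuron genes, 16 were marked (88.9%, interval 65.3 to 98.6), including Nr4a2 at 14.6 and Pitx3 at 8.56, both transcription factors of dopaminergic neurons. The unmarked members were Th, which encodes the rate-limiting enzyme of dopamine synthesis, and Aldh1a1. Th had a promoter peak in each replicate's own list but none in the replicated list, and Aldh1a1 had none in any list. Of 10 serotonergic neuron genes, 7 were marked, led by Gata3 at 12.5 and Gata2 at 9.53, while Tph2, which encodes the serotonin-synthesising enzyme of neurons, had no peak in any list and Fev had peaks only in the replicate and pooled lists.

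Genes of growth and signalling were likewise marked. All 24 cell cycle genes (led by Hmgb2 at 22.7 and Aurka at 19.8), all 24 housekeeping genes (Ywhaz at 39.3, Actb at 37.2), all 24 signalling pathway genes (Ptch1 at 25.5, Axin2 at 24.5) and all 12 immediate early genes (Dusp1 at 22.3, Jun at 16.6) had a peak.

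Genes of 9 lists, Hox, microglia, erythroid cells and 6 other tissues, were marked less often than all other genes. A gene is called unmarked where the replicated list has no promoter peak. Among the unmarked genes named, Th, Fev, Tbr1, Cx3cr1 and Sox10 had one in each replicate's own list and in the pooled list. Afp, Col1a2 and Csf1r had one in the lists of replicate 1 and the pooled samples, Myod1, Gata4, Pecam1 and S100b in that of replicate 1 only, and Aqp4 and Nkx2-5 in the pooled list only. Of the 39 Hox genes, which pattern the hindbrain and spinal cord, 4 were marked (10.3%, interval 2.87 to 24.2), against 8 in replicate 1's own list and 4 in replicate 2's, Hoxa7 at 5.80 and Hoxd1 at 3.44 the strongest, with Hoxa2, Hoxa3 and Hoxb4 unmarked in every list. Marked shares were 3 of 19 for the germline (15.8%), with Dazl at 5.79 and Spaca1 at 5.12, and Ddx4 and Sycp3 unmarked. They were 4 of 20 for the liver (20.0%; 7 in replicate 1's own list), 5 of 18 for gut and pancreas (27.8%) and 5 of 17 for microglia and macrophages (29.4%). In the liver list, Alb, the albumin gene, had no peak in any list and Afp none in the replicated list, whereas Foxa3 (20.2, not within 0.5 kb) and Apoh (16.5) were marked by peaks that lie in the window of another gene too. In the gut and pancreas list Lgr5 (9.25) and Nkx2-2 (5.33), a gene also used in the ventral neural tube and held by the midbrain list, were marked and Cdx2 and Pdx1 were not. Among microglial genes Hexb (8.34) and Irf8 (6.33) were marked, and Csf1r and Cx3cr1 were not in the replicated list. The share was 6 of 20 for skeletal muscle (30.0%; 10 in replicate 1's own list), 6 of 18 for heart (10 and 8 in the lists of replicates 1 and 2), 6 of 18 for epidermis (33.3% each) and 6 of 17 for erythroid genes (35.3%). The strongest members were Mylpf (25.2, in a shared window) and Actn2 (9.95) for muscle, Myl4 (30.2, in a shared window) and Ryr2 (10.4) for heart, Lor (16.1, with no promoter peak in replicate 2's own list or within 0.5 kb) and Krt10 (14.0) for epidermis and Ank1 (16.5) and Tal1 (7.93), which is also a GABAergic lineage gene, for erythroid cells. The unmarked members included Myod1 and Myf5, the muscle determination genes, Nkx2-5 and Gata4 in the heart list, Krt5 and Krt14 in the epidermis list, and the globin genes Hbb-y, Hba-a1 and Hba-a2.

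Of the 27 lists, 10 had a larger marked share than all other genes, 9 a smaller one and 8 did not pass (two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 27 lists). Adjusted p was 0.000137 for the neural progenitor, postmitotic neuron, midbrain patterning, cell cycle, housekeeping and signalling lists, 0.00223 for proneural, 0.00432 for GABAergic, 0.00638 for glutamatergic and 0.0169 for immediate early genes. It was 3.68e-11 for Hox, 0.000137 for liver and for germline, 0.00396 for muscle, 0.00405 for gut and pancreas, 0.00638 for microglia, 0.0169 for heart and for epidermis, and 0.0262 for erythroid genes. The lists that did not pass were dopaminergic (0.0605), forebrain (0.389), astrocyte (0.496), oligodendrocyte (0.691), hindbrain (0.691), endothelial (0.870), serotonergic (1) and mesenchyme and pericyte (1). Of these, 11 of 14 astrocyte genes were marked (Nfib at 22.1, away from the gene's 5' end, and Nfia at 21.8, with Gfap at 2.53, which had no peak in replicate 1's own list or within 0.5 kb, and Aqp4 and S100b unmarked), 10 of 17 oligodendrocyte genes (Mbp at 16.4, Ugt8a at 9.11, Olig2 at 3.79, with Sox10 unmarked in the replicated list only and Plp1 in every list), 11 of 18 endothelial genes (Mfsd2a at 14.2, Fli1 at 10.5, with Pecam1 and Cdh5 unmarked) and 12 of 18 mesenchyme and pericyte genes (Foxd1 at 7.85, Twist1 at 7.71, Col1a1 at 2.60, not within 0.5 kb, with Col1a2 and Col3a1 unmarked).

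Set against genes of like promoter CpG ratio rather than all genes, 9 of the 10 higher shares and 6 of the 9 lower ones (microglia, erythroid, muscle, heart, liver and epidermis) no longer passed. All of these higher lists but the proneural one were 100% marked, against expected shares of 89.2 to 96.6%. Even that highest possible share did not pass at their sizes, so the lost calls do not show that these lists equal genes of like CpG ratio. The postmitotic neuron list kept its call, with 100% marked against 78.4% (permutation test, adjusted p = 0.00216), and among lower shares those of Hox (88.5% expected, adjusted p = 0.00027), germline (57.3%, adjusted p = 0.00027) and gut and pancreas (54.6%, adjusted p = 0.00842) did. The hindbrain list, with 12 of 16 marked, lay below its expectation of 97.6% in that permutation test (adjusted p = 0.00526). The erythroid list lay 0.913 percentage points above its own. The other lists that lost a lower call stayed below theirs. Muscle stood at 30.0% against 50.8%, heart at 33.3% against 55.1% (permutation test, adjusted p = 0.0517) and liver at 20.0% against 38.4%. Microglia stood at 29.4% and epidermis at 33.3%, each against 41.6%. Counting only peaks with at least 50% of their length in the window left 3 higher lists, cell cycle, housekeeping and immediate early. That setting cannot count a peak much wider than the window. The median domain was 8191 bp for GABAergic and 10493.5 bp for glutamatergic genes, against 2898 bp for cell cycle genes. The calls lost with it therefore cannot be told apart from an effect of peak width. With a single start site per gene the GABAergic and immediate early calls were lost. With the peaks of replicate 1 alone the muscle (Fisher's exact test, adjusted p = 0.133) and heart calls (0.386) were lost, with those of replicate 2 alone the heart call (0.0978), and and with either, as with the pooled list, the dopaminergic and forebrain lists passed as higher. The pooled list also ended the microglia (Fisher's exact test, adjusted p = 0.0929) and heart calls (0.161), a window of 2.5 kb the muscle (0.198) and heart calls (0.104), and leaving out genes that share a window the microglia and erythroid calls (0.0525 and 0.0613). The forebrain list passed as higher with a window of 2.5 kb too (Fisher's exact test, adjusted p = 0.0321), and the dopaminergic list without genes that share one (0.0225).

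**Figure D2:**
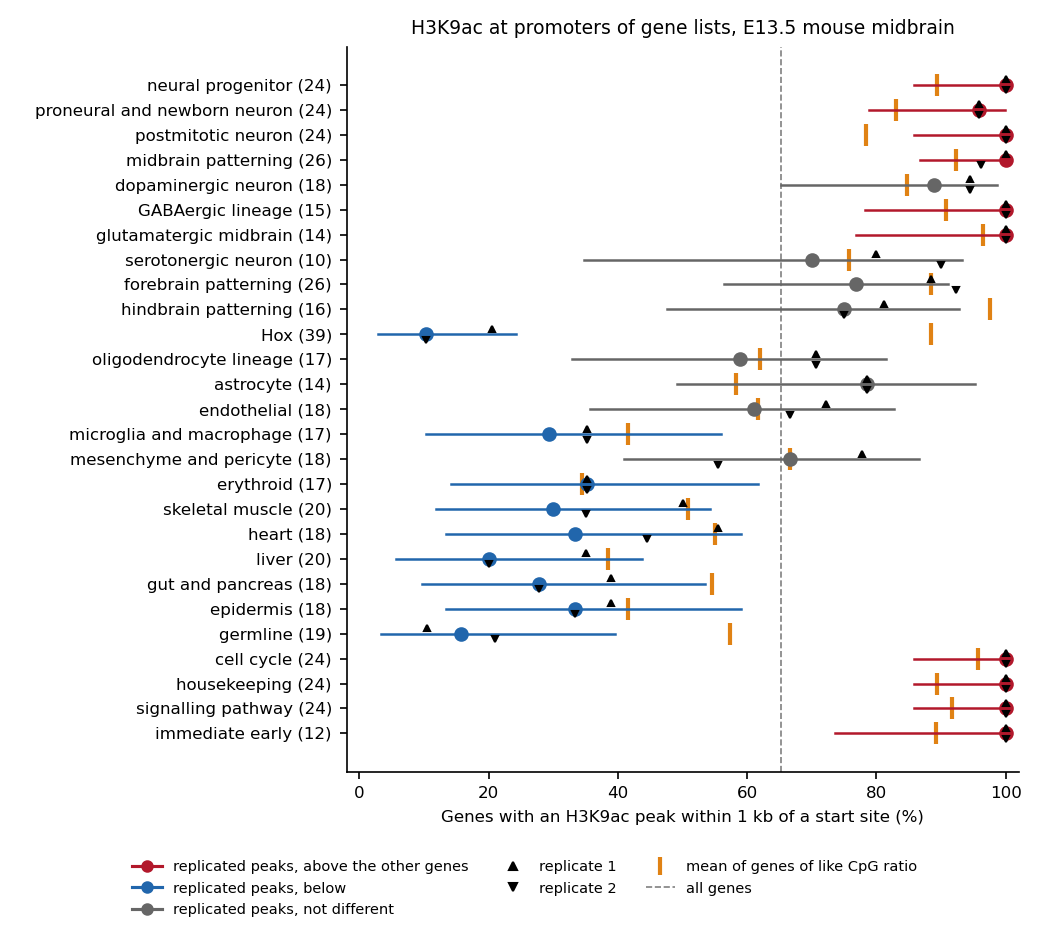
The percentage of each list's genes with an H3K9ac peak within 1 kb of a start site, with the number of genes in parentheses; circles and bars are the replicated peaks with 95% Clopper-Pearson intervals, triangles each replicate's own peak list, orange ticks the mean of genes of like promoter CpG ratio, and the dashed line all genes (65.2%). The 10 lists in red sit at 95.8 to 100%, Hox at 10.3% and the 8 other lists in blue at 15.8 to 35.3%.

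H3K9ac domains were wider at the marked genes of 10 lists, most of them of progenitors, neurons and the midbrain, than at other marked genes, and narrower at those of 5. Replicated peaks less than 1 kb apart were joined, and a marked gene then had a median domain of 2058.5 bp (quartiles 1314 and 3037 bp). The widest, 30654 bp, lay over Pou3f3, a transcription factor gene of the glutamatergic list, on chromosome 1 from 42683944 to 42714597. It was followed by Nr2f2 (28412 bp), Zfhx3 (25544 bp), Tcf7l2 (24180 bp), Ebf3 (23692 bp), Mn1 (21802 bp), Lhx1 (21623 bp, a domain that also takes in a start site of Aatf), Lhx2 (21377 bp) and Zic1 (21343 bp). Otx2 lay in a domain of 20059 bp, Sox2 in one of 18815 bp and En1 in one of 14426 bp, whereas Foxg1, which drives forebrain development, had 546 bp. Foxg1 does not stand for the forebrain list, where Bcl11b had 9829 bp, Emx2 7609 bp and Dlx2 3772 bp. In the midbrain list Foxa2 had 3296 bp.

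Domains of the glutamatergic midbrain list were 3.99 times as wide as those of other marked genes by geometric mean, with a median of 10493.5 bp. When no gap was joined, the log2 ratio of this list was 1.34 in place of 2.00. The neural progenitor list stood at 2.91 times, GABAergic at 2.87, proneural at 2.49, signalling at 2.26, postmitotic neuron at 2.02 and midbrain patterning at 1.94 (all 7 with adjusted p = 6.86e-05 from the smallest p that 100000 permutations can give). Domains were also wider in the dopaminergic (1.66 times, adjusted p = 0.00466), immediate early (1.61 times, adjusted p = 0.0199) and housekeeping lists (1.45 times, adjusted p = 0.0114) in the permutation tests. They were narrower in the microglia (0.277 times, adjusted p = 0.00024, 5 genes), muscle (0.413, adjusted p = 0.00476, 6 genes), heart (0.493, adjusted p = 0.0199, 6 genes), mesenchyme and pericyte (0.520, adjusted p = 0.00283, 12 genes) and oligodendrocyte lists (0.562, adjusted p = 0.0173, 10 genes), by two-sided permutation tests adjusted over the 24 lists with at least 5 marked genes. No difference passed the permutation test for the serotonergic (adjusted p = 0.155), forebrain (0.324), hindbrain (0.0891), astrocyte (0.321), endothelial (0.218), erythroid (0.175), gut and pancreas (0.0856), epidermis (0.111) and cell cycle lists (0.133). In each replicate's own peaks the first 7 lists were wider again, at log2 ratios of 1.51 and 1.49 for GABAergic genes and 1.11 and 1.17 for midbrain genes in replicates 2 and 1. The dopaminergic call was lost in replicate 2's peaks (log2 ratio 0.47, permutation test, adjusted p = 0.101) and in the pooled list. Also lost were the muscle and mesenchyme calls in the pooled list, the heart call among peaks that overlap both replicates and with a single start site per gene (permutation test, adjusted p = 0.119), and the dopaminergic, housekeeping, immediate early and oligodendrocyte calls when no gap was joined. Leaving replicate 2 out raised the number of narrower lists from 5 to 8, although by permutation test the oligodendrocyte (adjusted p = 0.0514) and mesenchyme calls (0.172) were then lost and the heart log2 ratio went from -1.02 to -1.82. The 2 counts cover different lists. Hox and liver genes, with 8 and 7 marked in replicate 1's own list, had too few marked genes in the replicated list to be tested. Among the 24 lists, those that passed by permutation test only under other settings were epidermis as narrower in the peaks of replicate 1 (adjusted p = 0.0287), those of replicate 2 (0.0413) and with a single start site per gene (0.0158), and erythroid in those of replicate 2 (0.0413). Endothelial genes passed as narrower in the peaks of replicate 1 (permutation test, adjusted p = 0.0320), as did gut and pancreas genes (0.0287), which also passed in the pooled list (0.0414), with a single start site (0.0201) and matched on CpG ratio (0.0269). Cell cycle genes passed as wider in the pooled list (permutation test, adjusted p = 0.0154) and in replicate 2's peaks (0.0176), and forebrain genes with gaps of 2.5 kb joined (0.0138). Hindbrain genes passed as wider in the pooled list (permutation test, adjusted p = 0.0470), in replicate 1's peaks (0.0400), with a window of 0.5 kb (0.0277) and with a single start site (0.0255).

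**Figure D3:**
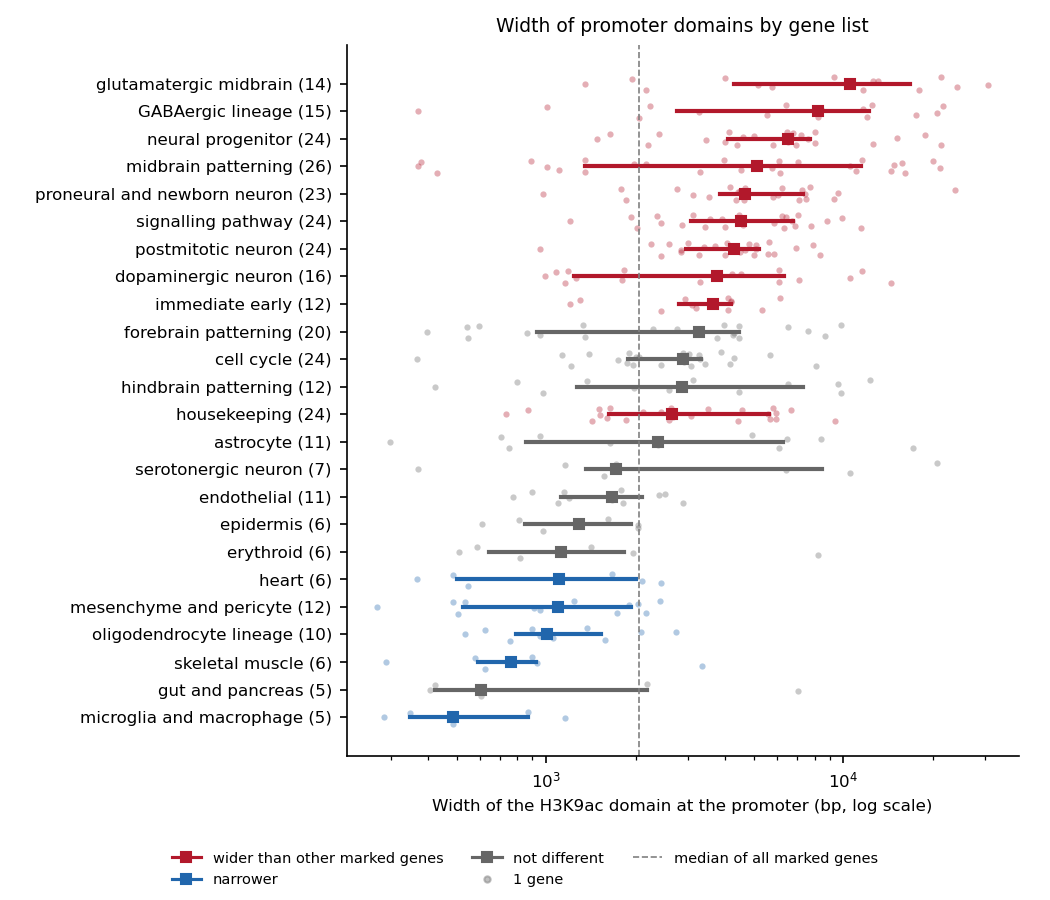
Width of the H3K9ac domain at the promoter (x axis, bp, log scale) for the marked genes of each list, with the number of genes in parentheses; dots are genes, squares medians and bars the quartiles, and the dashed line is the median of all marked genes (2058.5 bp). Medians run from 10493.5 bp in the glutamatergic list to 486 bp in the microglia list.

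Distal peaks were more numerous around the genes of 12 lists than around other genes, and fewer around the Hox genes. A distal peak can lie within the gene or in the same joined domain as its promoter peak. These counts and the domain widths are therefore not independent measures. A gene of the midbrain patterning list had 5.31 ± 4.65 distal peaks (mean ± SD over 26 genes) whose nearest start site within 100 kb was its own, against a mean of 0.851 for other genes. En2, Lmx1b and Otx2 had 12 each and En1 10. With other peak lists, which hold more distal peaks, this excess of 4.46 over other genes was 8.33 without replicate 1, 8.97 without replicate 2 and 9.10 in the pooled list. That of postmitotic neuron genes was 7.22, 8.04 and 10.5 in place of 3.40, but 1.98 with a single start site per gene. All 12 lists with more distal peaks had a larger excess with these 3 peak lists. The GABAergic list had 4.53 ± 4.49, glutamatergic 4.50 ± 4.42, proneural 4.33 ± 4.50, neural progenitor 4.29 ± 4.50, postmitotic neuron 4.25 ± 7.43, signalling 4.12 ± 3.76 and dopaminergic 3.78 ± 5.08. Immediate early (3.25 ± 2.01), forebrain (2.85 ± 3.53), astrocyte (2.79 ± 2.75) and hindbrain genes (2.75 ± 2.02) also had more than other genes, and the Hox list fewer, 0.0769 ± 0.354 (a difference of -0.781, and of -1.76 and -2.14 without replicate 1 and 2). The genes with the most distal peaks were Gse1 with 77, Zmiz1 with 49, Ncor2 and Ssbp3 with 34 each and Ephb2 with 33.

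By permutation tests over 27 lists, adjusted p was 0.00054 for midbrain, 0.00108 for Hox, 0.00335 for proneural, progenitor and postmitotic neuron, 0.00423 for signalling, 0.00609 for GABAergic, 0.00702 for glutamatergic, 0.00744 for dopaminergic, 0.0111 for forebrain, 0.0319 for immediate early, 0.0347 for hindbrain and 0.0417 for astrocyte genes. The other 14 lists did not pass the permutation test, among them liver (0.200 ± 0.410, adjusted p = 0.101), oligodendrocyte (1.35 ± 1.58, adjusted p = 0.451), serotonergic (1.90 ± 3.70, adjusted p = 0.254), endothelial (0.722 ± 0.826, adjusted p = 1), cell cycle (1.33 ± 1.43, adjusted p = 0.413) and housekeeping genes (1.00 ± 1.29, adjusted p = 0.724). Matching on the length of genome nearest to each gene raised the expected mean to 1.42 for midbrain genes and 1.27 for progenitor genes and lowered it to 0.404 for Hox genes, whose difference shrank to -0.327 (permutation test, adjusted p = 0.0268). The hindbrain and astrocyte calls were lost with it (permutation test, adjusted p = 0.135 and 0.149), at an excess of 1.53 in place of 1.89 and 1.60 in place of 1.93, and also in the pooled list, where liver genes had fewer distal peaks (permutation test, adjusted p = 0.0475). With the peaks of replicate 2 alone the hindbrain call was lost (permutation test, adjusted p = 0.0581) and 3 lists, Hox, liver and germline, stood below in place of 1. With those of replicate 1 alone the astrocyte call was lost (permutation test, adjusted p = 0.0808).

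In the replicated list, genes that pattern the midbrain were marked more often than those that pattern the forebrain and hindbrain, but neither difference passed with the pooled list or with either replicate's own list. All 26 midbrain genes were marked against 20 of 26 forebrain genes (76.9%), among which Bcl11b (21.4), Emx2 (11.9), Dlx2 (6.73) and Foxg1 (3.22) had peaks. Six6 had none in any list, and Tbr1 had one in each replicate's own list and in the pooled list but not in the replicated list. Of genes in only one of the lists compared, 25 of 25 midbrain and 11 of 15 hindbrain genes (73.3%) were marked. Irx1 (26.5), Irx3 (26.1) and Gbx2 (6.31), which positions the boundary of midbrain and hindbrain, had peaks, and Phox2b and Lbx1 did not. The contrast was largest with the Hox genes (26 of 26 against 4 of 39), and forebrain genes also exceeded them (20 of 26 against 4 of 39).

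Over these 4 comparisons, two-sided Fisher's exact tests with Benjamini-Hochberg adjustment gave adjusted p of 0.0226 against forebrain, 0.0199 against hindbrain, 1.09e-13 against Hox and 9.84e-08 for forebrain against Hox. Only the Hox contrasts held with every other peak set. That with midbrain genes was 59.0 percentage points in place of 89.7 with 50% of the peak in the window, a setting that cannot count peaks much wider than the window. In each replicate's own list 88.5 and 92.3% of forebrain genes were marked, and the difference from midbrain genes was 11.5 percentage points without replicate 2 (Fisher's exact test, adjusted p = 0.235) and 3.85 without replicate 1 (adjusted p = 1), while that from hindbrain genes was 20.0 (adjusted p = 0.0614) and 22.7 (adjusted p = 0.0752).

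**Figure D4:**
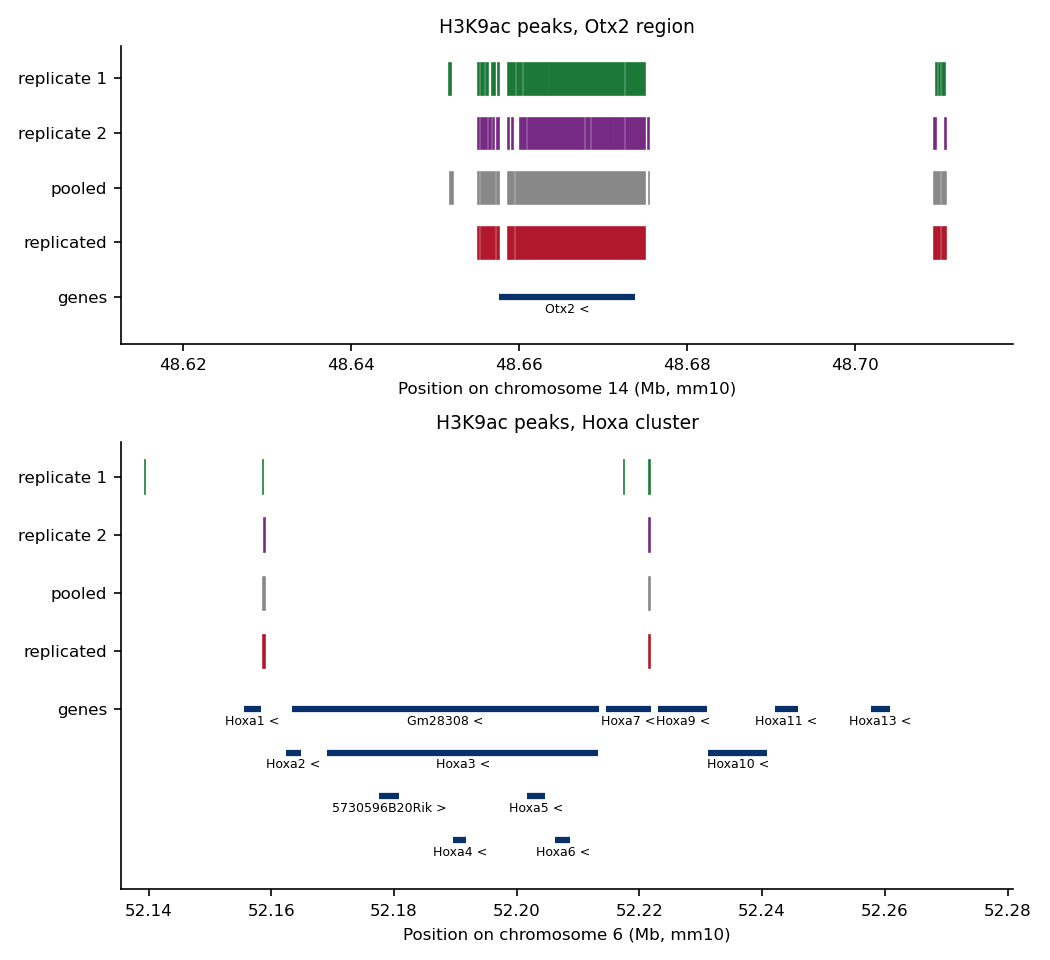
Positions of H3K9ac peaks in the 4 lists (coloured boxes) over protein-coding genes (blue bars, with > and < for the strand) in the Otx2 region on chromosome 14 and the Hoxa cluster on chromosome 6; the x axis is the position in Mb (mm10). The replicated peaks cover 20083 bp of the Otx2 region, in 8 peaks, and 713 bp of the Hoxa region, in 2 peaks.

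Genes on the X chromosome carried promoter H3K9ac less often than autosomal genes. Of 948 protein-coding genes on the X, 457 were marked (48.2%, interval 45.0 to 51.4), against 13826 of 20780 on autosomes (66.5%, interval 65.9 to 67.2). The X-linked neuronal gene Dcx was among those marked and the X-linked myelin gene Plp1 among those without a peak. The odds ratio was 0.468 (two-sided Fisher's exact test, p = 1.04e-29). The difference appeared at promoters with a high CpG ratio, 94.9% on the X against 98.4% (Fisher's exact test, p = 0.00478), and at those with a low one, 38.9% against 49.4% (p = 8.28e-09). It was present in each replicate's own list, at -19.4 percentage points in replicate 1 and -19.8 in replicate 2. Among genes whose promoter sequence is found once in the genome it narrowed to -8.35 percentage points.

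CpG-rich promoters were nearly always marked. Of 7435 genes with an observed to expected CpG ratio of at least 0.6 around the gene's 5' end, 7309 were marked (98.3%). Of 14476 with a lower ratio, 6977 were (48.2%). Midbrain genes such as En1 (ratio 0.733) and Lmx1b (0.829) belonged to the first class and the unmarked genes Th (0.159), Alb (0.260) and Hbb-y (0.122) to the second, although Hoxb4 (0.612) and Lbx1 (0.749) were CpG-rich and unmarked. The odds ratio was 62.3 (two-sided Fisher's exact test, p below what double precision can hold). The median ratio was 0.605 for marked and 0.168 for unmarked genes, and in each replicate's own list the difference between the classes was 46.9 and 47.9 percentage points. A gene could be marked at a start site other than its 5' end, as Nfib (ratio 0.296) was. The ratio is therefore not always that of the marked promoter.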

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

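In this part the tests of CpG content on the X chromosome, of CpG content among the marked members of lower lists and of weak calls between replicates were chosen only after the result was seen, as was the odds ratio that joins CpG content with unique promoters.

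Of the replicated peaks, 10 lay on 4 unplaced or unlocalised scaffolds, outside the chromosomes that the comparisons used. Apart from list totals, the candidate rule and the counts of replicated peaks that overlap each replicate, no comparison covered them. Their highest fold enrichment was 10.7 and their median 3.65. The pooled list held 13 such peaks and the lists of replicates 1 and 2 held 11 and 16.

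Fewer X-linked than autosomal promoters were marked. A lower CpG content of X promoters is argued against as the whole cause, since within quintiles of CpG ratio the Mantel-Haenszel odds ratio stayed at 0.518 (95% interval 0.429 to 0.625). Promoter sequence repeated elsewhere can hide a mark if only uniquely mapped reads are kept, which the sources used here do not say. As the whole cause by itself it is argued against likewise, by an odds ratio of 0.679 (0.578 to 0.797) among genes with unique promoters. However, only 71.0% of X genes against 89.7% of autosomal genes are of that kind. Taken jointly, unique promoters within CpG quintiles gave 0.787 (0.630 to 0.985), closer to 1 than either alone. The quintiles and the bound on unique sequence are coarse, so both together are not excluded as the whole cause. What remains is open, and no biological explanation was tested because the design holds no contrast of sex or tissue.

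Of the 186 genes in lists with a smaller marked share, 45 were marked all the same. Peaks that belong to a neighbouring gene are argued against for most of them: in 5 of the 45 (11.1%, interval 3.71 to 24.1), Mylpf, Ckm, Myl4, Foxa3 and Apoh, every promoter peak also lay in another gene's window, against 17.0% of other marked genes (Fisher's exact test, p = 0.424). For those 5 the neighbour stays open. Marked members had a median CpG ratio 0.269 higher than unmarked members (0.530 against 0.260, permutation p = 0.00026), so a higher CpG ratio is a candidate explanation for the marks, although the median of marked members lies under the limit of 0.6 for CpG-rich promoters. Cells of those tissues in the dissected midbrain were not tested for.

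Many peaks of one replicate had no partner in the other. Weak calls near the threshold stay open as an explanation: 100% of the strongest 10% of peaks in either replicate had a partner, but this was known from the overlap by strength before the test was chosen and adds no support of its own. The lowest overlap was not in the weakest 10% but in the next, and unpartnered peaks had a median fold enrichment of 2.85 in replicate 1 and 2.96 in replicate 2, against 4.52 and 4.31 for partnered ones. Regions split into separate calls cannot be told apart from true absence for unpartnered peaks close to a peak of the other replicate. Of all peaks, 72.8% of replicate 2's and 65.5% of replicate 1's lay within 1 kb of a peak of the other. At least 90% of both had been set as the bound for split calls and under 70% of both as the bound against them. These shares include the 56.8 and 47.2% of peaks that overlap one, so most unpartnered peaks lay more than 1 kb away. The peaks farther away cannot be split calls of a partner within that distance, and neither depth, which the lists do not give, nor a biological explanation was tested.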

How the results depend on the processing

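The settings that keep only peaks overlapping both replicates and that leave out shared or repeated promoters were chosen after the data were seen. No paired analysis was possible because there is only 1 group. Of 160 values of the main comparisons recomputed under the alternatives, 131 were counted as kept. A test result was kept if its direction and side of the threshold stayed the same. Counts of lists were held to a looser ratio bound, by which a fall of wider lists from 10 to 7 was kept. Correlations had to stay within the SD of the main values from replicate 1 and 2, which measures no sampling error. The 131 include the values with peaks merged within lists. Replicate overlap (31.8 to 66.7%), the promoter share (29.2 to 58.2%), promoter against distal replication (26.8 to 53.0 percentage points), X against autosomes (-20.3 to -8.35) and CpG classes (45.9 to 55.6) held in all their alternatives, and merging peaks within lists moved nothing, because no peaks there touch. The cause of the following changes was not tested except where stated. The correlation of fold enrichment, from replicate 1 and 2, moved to 0.805 and 0.774 with 50% of the peak overlapping, to 0.898 in both with 50% of both, to 0.779 and 0.758 with a −log10 q of at least 2, and to 0.776 from replicate 1 with equal numbers of peaks. The difference between midbrain and forebrain no longer passed at a −log10 q of at least 2 (19.2 percentage points), in the pooled list (3.85), with windows of 0.5 kb (19.2) and 2.5 kb (11.5), for peaks overlapping both replicates (15.4), with 50% of the peak in the window (7.69), and with 1 replicate left out (3.85 to 11.5). That between midbrain and hindbrain no longer passed at a −log10 q of at least 2 (22.7), in the pooled list (20.0), with a window of 2.5 kb (20.0), for peaks overlapping both replicates (18.7), with 50% of the peak in the window (25.3) and with 1 replicate left out (20.0 to 22.7). Lists with a larger marked share fell from 10 to 3 with 50% of the peak in the window and to 1 when matched on CpG ratio, where those with a smaller share fell from 9 to 4. Reversed were the GABAergic list with 50% of the peak in the window (-15.6 percentage points), and, matched on CpG ratio, the hindbrain (-22.6) and erythroid lists (0.913). Changes with 50% of the peak in the window cannot be told apart from an effect of peak width, since that setting cannot count very wide peaks. Narrower lists numbered 3 for peaks overlapping both replicates and 7 to 8 with 1 replicate left out, in place of 5. For peaks overlapping both replicates the heart call was lost, and the microglia list had too few marked genes to be tested. Without replicate 2, Hox and liver genes were tested too, which the main comparison left out. Lists with fewer distal peaks numbered 2 in the pooled list and 1 to 3 with 1 replicate left out, in place of 1. For single lists, 282 of 324 marking values, 235 of 263 width values and 285 of 297 distal values kept their call. Of 1032 values for 129 named genes 39 differed, in 19 genes. Depth is unknown from the lists, so what it limits was not tested.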

Other observations

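All tests in this part were chosen after values in the data had been seen.

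The strongest distal peaks lay at noncoding genes, several of them known from neural cells. Of the 20 strongest, 18 overlapped the 1 kb either side of a start site of an annotated long noncoding RNA or microRNA gene, and 9 had a microRNA within 5 kb. All 3 loci of miR-124, a microRNA of neurons, were among them: Mir124a-3 on chromosome 2 (180890095 to 180897155, fold enrichment 37.5), Mir124a-2 on chromosome 3 (17792493 to 17798145, 30.6, beside a peak from 17784664 to 17792303 at the start of its host gene, 35.3) and Mir124a-1 on chromosome 14 (64585186 to 64596152, 34.2). So were a peak on chromosome 13 (83724044 to 83734522, 34.3) at the start of C130071C03Rik and within 5 kb of Mir9-2, and one at Mir9-3 on chromosome 7 (79498904 to 79512211, 29.4). Both are microRNA genes of neural progenitors. Peaks also lay at Mirlet7i on chromosome 10 (26.5) and at the Mir17 cluster on chromosome 14 (25.7). Long noncoding genes among the 20 included Malat1 on chromosome 19 (28.5), Miat on chromosome 5 (25.6) and Rmst on chromosome 10 (24.7). The strongest distal peak of all, near Rhof, held start sites of AI480526 and 4932422M17Rik. Among the strongest 10% of distal peaks, 488 of 2078 (23.5%, interval 21.7 to 25.4) overlapped such a noncoding start site, against 5.76% of the other distal peaks (two-sided Fisher's exact test, p = 2.26e-132). Over all 20786 distal peaks, 1565 (7.53%) did. The 20 strongest were 1459 to 13308 bp wide, against a median of 481 bp over all distal peaks. A wider peak meets a given window more often by position alone, and the comparison was not matched on peak width.

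Gene families differed widely in their marked share. Of 1134 olfactory receptor genes only Olfr94 was marked (0.0882%, interval 0.00223 to 0.490), and of 328 vomeronasal receptor genes only Vmn1r4 (0.305%). No member of 42 beta defensin genes had a peak, which allows a share of up to 8.41%. Keratin-associated genes were marked in 1 of 57 cases and keratin genes in 6 of 53 (11.3%), among them Krt8, Krt18 and Krt222. In contrast 78 of 81 ribosomal protein genes (96.3%) were marked, the exceptions being Rpl10l, Rpl39l and Rpl3l, together with 45 of 46 genes of NADH dehydrogenase subunits (all but Ndufa4l2), 38 of 40 of the proteasome (all but Psma8 and Psmb11), 338 of 394 zinc finger genes named Zfp (85.8%), 58 of 67 histone genes (86.6%), 18 of 19 Sox genes (all but Sox10, which had a promoter peak in each replicate's own list and in the pooled list) all 12 LIM homeobox genes and 265 of 371 solute carrier genes (71.4%). Adjusted p was 0.00825 for Sox genes and 0.0130 for LIM homeobox and for solute carrier genes. Sox genes had 4.16 distal peaks on average and LIM homeobox genes 3.83. The clustered protocadherins, cell adhesion genes of neurons, were marked in 10 of 56 cases (17.9%, interval 8.91 to 30.4). Of 16 families tested against all other genes by Fisher's exact test with Benjamini-Hochberg adjustment, 8 were higher, 6 lower and 2, Fox (32 of 44) and POU (11 of 16), did not pass. Only 46.6% of vomeronasal and 41.8% of histone genes have a promoter whose sequence is found once in the genome, against 83.5% of olfactory receptor and 96.4% of protocadherin genes, so the first 2 counts are uncertain. The median promoter CpG ratio was 0.109 for olfactory receptor, 0.107 for vomeronasal and 0.134 for beta defensin genes. It was 0.479 for protocadherin, 0.680 for ribosomal protein and 0.722 for Sox genes. Families were not matched on CpG ratio, so their differences cannot be told apart from an effect of CpG content.

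CpG-rich promoters without a peak in the replicated list were few, 126 of 7435, and Hox genes stood out among them. Of 19 CpG-rich Hox genes 2 were marked (10.5%, interval 1.30 to 33.1), against 7307 of 7416 other CpG-rich genes (98.5%, two-sided Fisher's exact test, p = 4.29e-29). The 126 also held 11 clustered protocadherin genes and 6 Fox genes (Foxc2, Foxd3, Foxe1, Foxe3, Foxf1 and Foxl1). These 6 Fox genes all had a promoter peak in the pooled list and in a replicate's own list. So did Hoxd3, Hoxd4, Hoxd9 and Hoxd13, while the other Hox genes among the 126 had none in any list. In any of the fixed lists were 27 of the 126, the 17 Hox genes included. In 44 of the 126 the promoter sequence is repeated elsewhere in the genome, and in 82 it is not.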
